A study of Mus musculus with 2 samples.

How the data were processed

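The deposited files hold, per the labels, 2 Stereo-seq libraries of mouse heart, 1 with Clu overexpressed (AAV-Clu) and 1 with GFP overexpressed (AAV-GFP). The vector was given at postnatal day 4, the apex was resected at postnatal day 8, and sections of 10 µm were taken 3 days after the injury. The deposited values are raw MID counts, 1 count for each gene at each DNB position, with no normalization by the authors. The submitters' processing notes name the builds mm10 and GRCm38. The aligner, the counter, the gene annotation, any filter and the treatment of intronic reads are not given in the sources used here. The spacing of the DNBs is not given either, so distances are in positions. Whether positions were restricted before deposit is also not stated in those sources.

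MIDs were summed into bins of 50 by 50 positions, and bins of at least 200 MIDs were kept, which retained 99.98% of MIDs in each library. Depth was 154737745 MIDs for AAV-Clu and 171017516 for AAV-GFP, so counting error is small for abundant genes and the absence of replicates limits every comparison. Levels are counts scaled to 1000000 MIDs of a library or region (CPM), and 0.5 MID was added to each sum for log2 ratios of AAV-Clu over AAV-GFP. Levels carry exact Poisson intervals and ratios exact conditional (Clopper-Pearson) intervals, both at 95% and for counting error only. Shares of bins carry exact Clopper-Pearson binomial intervals at 95%, which treat bins as independent although bins within a section are not. With 1 library per group there was no test, no p-value and no count of changed genes. A gene is called higher or lower only at a ratio of at least 1.5, or the inverse, with an interval that excludes 1.

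The comparisons, the regions, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are Clu and the 12 genes of largest and 12 of smallest log2 ratio among those with at least 50 CPM in either library and an interval that excludes 1. Mitochondrially encoded, haemoglobin and predicted genes were left out of that rule. The text and plot leave out 1 of the 12 genes of largest ratio, which still counts in the summaries of these genes. For each list described, up to 4 members of largest absolute log2 ratio with at least 10 CPM could be named. Genes outside these rules, such as Gm42418, Trem2, Gpnmb as a region's leading gene and the genes of the distance profile, were chosen after their values were seen or by another rule that the text gives. There were 48 lists of muscle, metabolism, immune, stromal, stress and check genes with 823 members in all. A list's median log2 ratio over members of at least 20 MIDs was set against 10000 random lists of the same size, matched on expression in 20 bins, and it stood apart below percentile 1 or above percentile 99. Of these, 46 lists had at least 5 measured members and so a percentile. The choice of the 13 lists that lead the text was made after a look at the values.

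Regions came from k-means with 8 clusters on 20 principal components of 2000 variable genes in log-transformed bins of both libraries together. Each gene was centred within its library, and Clu, mitochondrially encoded, haemoglobin, ribosomal protein and sex-linked genes were left out of the features. Regions are numbered by size and described by their leading genes, which follow from how the bins were grouped, even where they were not among the features, and are not findings. The macrophage-richest region (8) and the contractile-richest region (1) were picked by the summed levels of those lists. No cell was segmented and no doublet caller was used, since a bin can hold several cells. For Clu-rich bins, bins of 100 by 100 positions were thinned to 13477 MIDs, which left out 1737 shallower bins of AAV-Clu and 1725 of AAV-GFP. The top 10% by Clu were 695 of 6946 bins in AAV-Clu and 798 of 7981 in AAV-GFP, and they were compared with the rest of the same library.

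The maps showed 2 heart sections in each file, and splitting them into tissue pieces, the 4 pairings across libraries, random lists matched on genomic gene length (8 bins of expression and 5 of length) and the distance profile were added after the data were seen. The pool of random genes held the members of the list itself, with and without length matching. Gene lengths were taken from the RefSeq annotation of GRCm38. For the test of length the 12 highest genes were picked anew in 1 pairing of pieces and measured in the pairing of the other pieces. The alternatives fixed beforehand changed the scaling, the bins kept, the depth, the region makeup, the filter and summary of the lists, the clustering and the settings for Clu-rich bins. Other scalings moved all log2 ratios by 0.02 to 0.06.

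The size rule and the list percentiles were tested on simulated data with the depths of these libraries. Among 2964 simulated genes, 200 of them changed, all changes of 2-fold and 0.5-fold passed the size rule, and 0% of changes of 1.3-fold or 0.769-fold and 0% of unchanged genes did. Intervals held the true ratio for 94.8% of unchanged genes. Of 46 simulated lists without change 1 fell outside percentiles 1 to 99, and 4 of 4 lists moved by less than 1.3-fold rose above 99. These simulations hold counting error and no difference between animals. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the trimmed mean of M values (TMM).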

Results

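The series asks how clusterin (Clu, a secreted chaperone) made by injured heart muscle cells bears on macrophages during regeneration. Spatial transcriptomes were measured by Stereo-seq, in which a tissue section is laid on a chip of DNA nanoballs (DNBs) whose barcodes give each captured RNA a position, and RNA molecules are counted by their molecular identifiers (MIDs). Mouse hearts received the vector at postnatal day 4, lost their apex by resection at postnatal day 8 and were collected 3 days later. There was 1 library per group, so every difference below describes these libraries, and the intervals of levels and ratios cover counting error only. Each library held 2 separate heart sections, called tissue pieces here. The labels do not say whether they came from separate animals, and their values stand side by side without being treated as replicates. The library labelled AAV-Clu held 154737745 MIDs in 33901 kept bins of 50 by 50 positions, and the library labelled AAV-GFP held 171017516 MIDs in 37813 bins. The median bin held 4529 MIDs and 1623 genes in the former and 4645 MIDs and 1749 genes in the latter, and a bin can hold several cells.

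Clu itself, the gene that the label says was overexpressed, did not follow the label. It was counted at 338 CPM (counts scaled to a depth of 1000000 MIDs, 95% Poisson interval 335 to 341) in the library labelled AAV-Clu and at 399 (396 to 402) in the library labelled AAV-GFP. The ratio of AAV-Clu over AAV-GFP was 0.848 (0.838 to 0.857). The tissue pieces gave 372 and 307 against 403 and 394. In region 4, with Clu among its leading genes, the levels were close, at 628 against 639, a ratio of 0.984 (0.961 to 1.01). In region 5, led by the atrial genes Fgf12, Mybphl and Bmp10, Clu was lower in the library labelled AAV-Clu, at 404 against 706, a ratio of 0.573 (0.549 to 0.597). Within region 1, the region richest in contractile genes, Clu stood at 207 against 269 CPM, a ratio of 0.770 (0.751 to 0.789). The macrophage-richest region 8 ran the other way, with 1360 (1328 to 1393) against 946 (924 to 968) and a ratio of 1.44 (1.39 to 1.49), which was 1.16 with regions made without centring. That ratio rested on tissue piece 1 of the library labelled AAV-Clu, whose level was 1701, against 1060 in its piece 2 and 865 and 1083 in the AAV-GFP pieces. The sources used here do not say whether transcripts of the vector would be counted under Clu, and GFP does not occur among the 27598 gene names. All directions below are therefore tied to the labels as given.

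**Figure D1:**
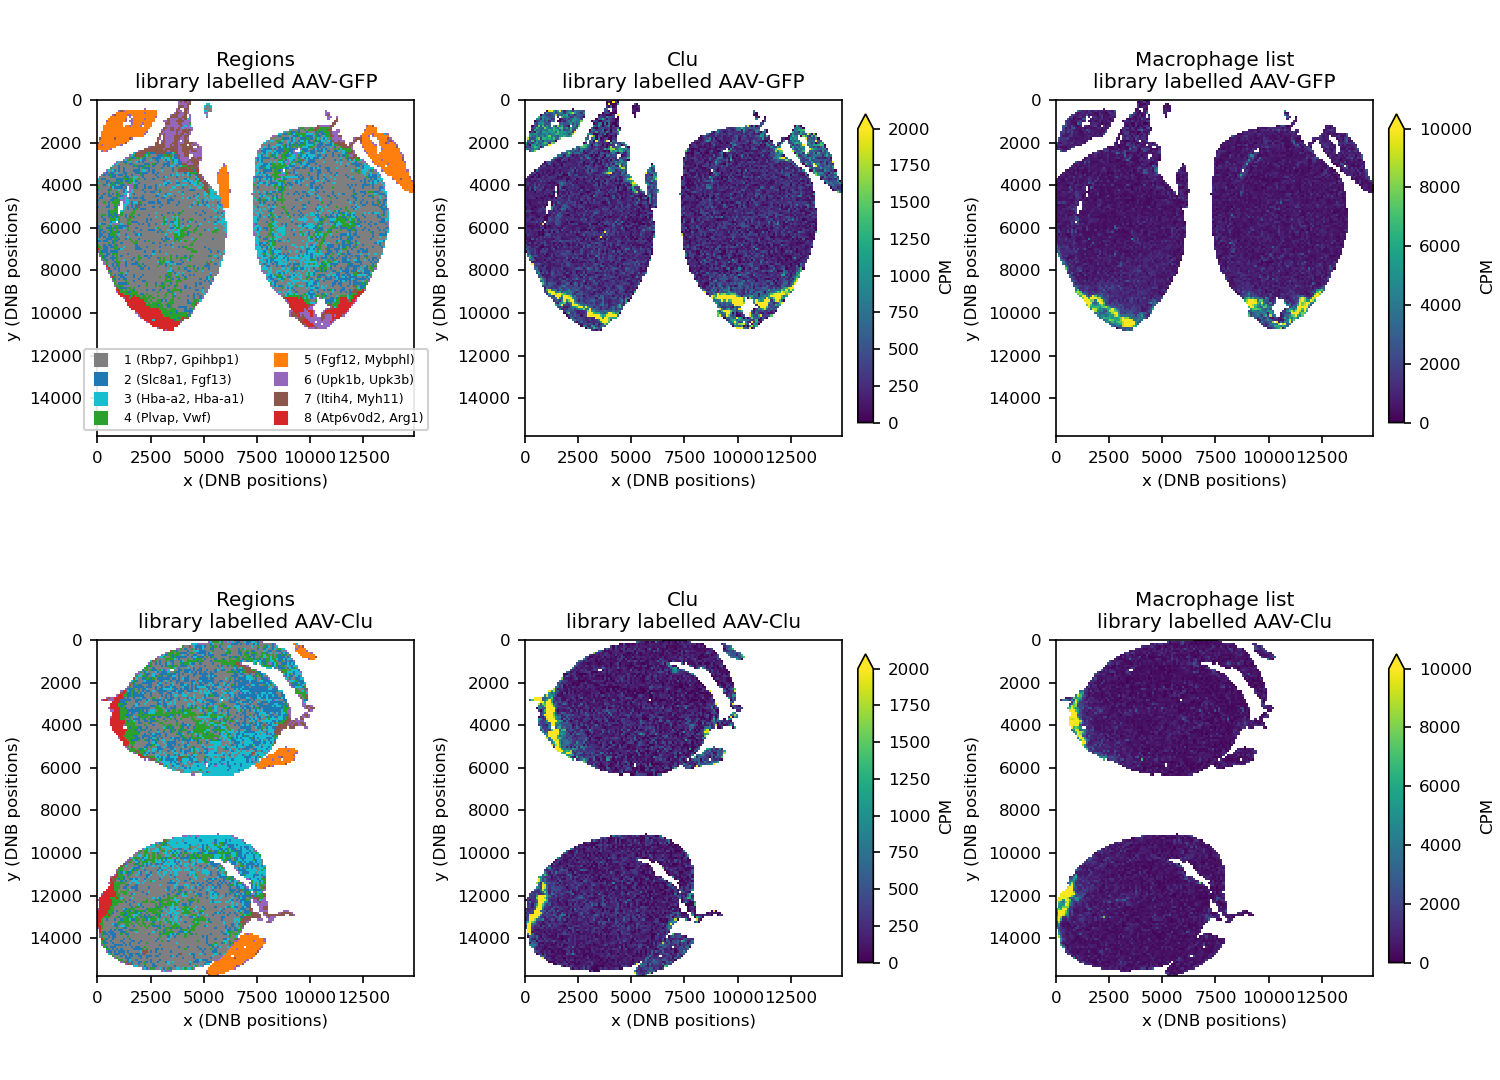
Maps of both libraries in DNB positions, drawn in bins of 100 by 100 positions: region (colour, with leading genes), Clu and the macrophage list (CPM, colour scales closed at 2000 and 10000, with higher bins in the last colour). Clu lies as a band along the edge of region 8 in all 4 tissue pieces, and region 8 held 2.40% of bins in the library labelled AAV-Clu and 3.44% in the library labelled AAV-GFP.

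Genes of macrophages that take up debris and of neutrophils were lower in the library labelled AAV-Clu. Spp1 (osteopontin) was counted at 264 against 773 CPM, a ratio of 0.342 (0.338 to 0.345). Lgals3 (galectin-3) stood at 46.8 against 124, and the neutrophil alarmins S100a8 and S100a9 at 62.8 against 215 and 54.8 against 167. S100a4 and Fxyd5 were lower as well, with log2 ratios of -0.85 and -0.80. Genes of atrial muscle filled most of the other places at this end. The growth factor Bmp10 was counted at 4.94 against 61.4, a log2 ratio of -3.63, with 8.98 and 1.27 in the AAV-Clu pieces against 101 and 18.1 in the AAV-GFP pieces. Sln, Myl4, Myl7 and Nppa had log2 ratios of -0.94, -0.80, -0.77 and -0.75, and Acta1 (skeletal actin) -0.86. Region 5 held 3.76% of bins in the library labelled AAV-Clu and 6.50% in the library labelled AAV-GFP, with 2.58% and 5.02% against 7.57% and 5.50% in the pieces. In region 1 the log2 ratios were -1.75 for Spp1, -1.37 for Lgals3, -1.74 for S100a8 and -1.55 for S100a9. The atrial genes Bmp10, Sln, Myl4 and Myl7 were low there too, at -3.71, -1.02, -0.95 and -0.85. In region 8 they stood at -3.14, -0.91, -1.09 and -0.88. Nppa and Acta1 changed sign in region 8, at 0.29 and 0.19.

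The 12 genes with the largest ratios were mostly abundant in both libraries. Il31ra (an interleukin receptor subunit) was counted at 3545 against 1390 CPM and Camk1d (a calmodulin-dependent kinase) at 5027 against 1982, with log2 ratios of 1.35 and 1.34. Lars2 (a mitochondrial tRNA synthetase) stood at 6377 against 2969, Zc3h7a at 4404 against 2042, Gphn at 3828 against 1814 and Cdk8 at 5678 against 3126. Cd44 (a hyaluronan receptor) had a log2 ratio of 1.19, Tmtc2 of 1.19, Jarid2 of 1.12 and Cmss1 of 1.02. C3, the central complement component, was counted at 85.3 against 45.5. Gm42418, a predicted gene that overlaps ribosomal RNA sequence, moved with them, at 80872 CPM against 54073. Across bins of 200 positions the median Spearman rho of the 12 genes with Gm42418 was 0.82 in the library labelled AAV-Clu and 0.73 in the other, against -0.13 and -0.09 for matched random genes. Ratios also went with genomic gene length, with a rho of 0.45 across 11947 genes, which are not independent replicates. All 24 genes at either end of the ratios had both AAV-Clu pieces on 1 side of both AAV-GFP pieces. Such separation was common, with a share of 73.4% among 3125 genes of at least 50 CPM.

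**Figure D2:**
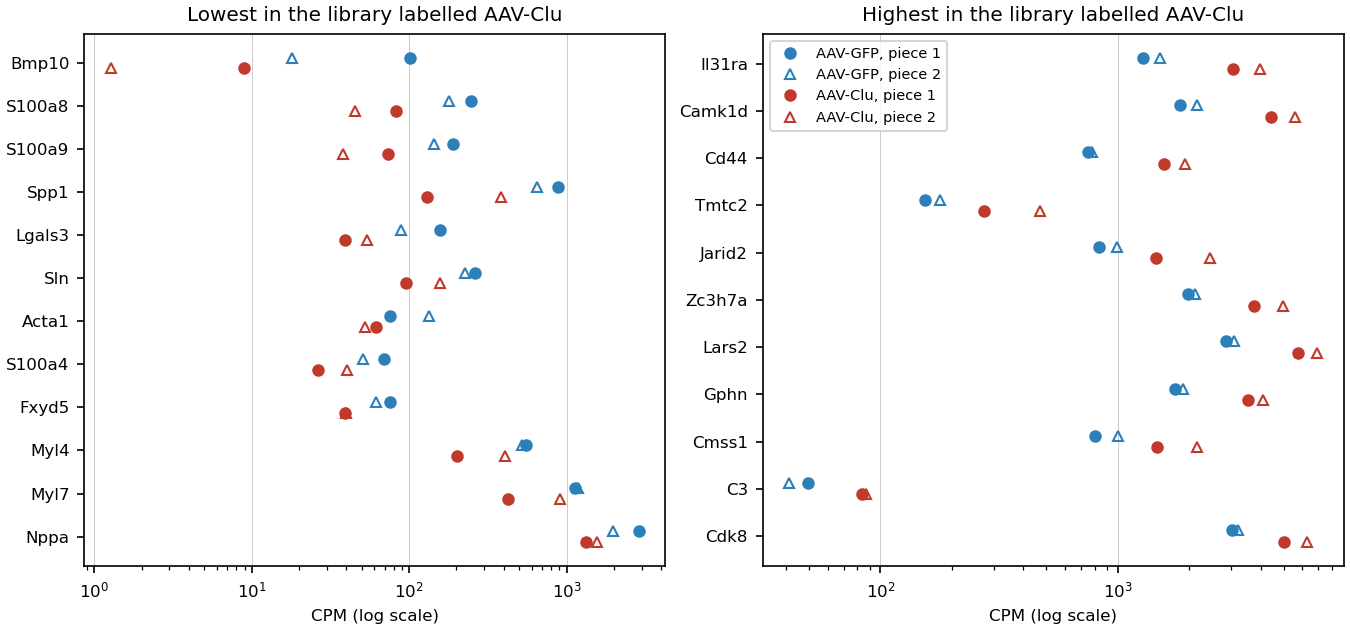
CPM (log axis) in each tissue piece of the genes at either end that the text names, with colour for the library label, circles for piece 1 and triangles for piece 2. Spp1 lies at 129 and 386 in the AAV-Clu pieces and at 889 and 648 in the AAV-GFP pieces.

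Most immune gene lists stood low in the library labelled AAV-Clu. Of the 20 macrophage genes 18 had a log2 ratio under 0 and 4 were at least 1.5-fold lower, among them Cd68 (11.7 against 22.2 CPM), Fcer1g (38.1 against 60.1) and Tyrobp (60.8 against 92.6). The list's median was -0.27, at percentile 0 among 10000 expression-matched random lists. Neutrophil genes stood lowest of these, with 11 of 14 at least 1.5-fold lower and a median of -1.58 at percentile 0, as in Ngp (5.04 against 17.6) and Retnlg (5.39 against 17.4). The list of lysosome, phagocytosis and lipid export genes had a median of -0.30 at percentile 0, and Gpnmb (13.5 against 46.8) and Msr1, a scavenger receptor (4.72 against 11.4), were lower. It shares Spp1 with the matrix list, Trem2 and Mertk with the macrophage list and Hmox1 with the antioxidant list. Trem2 is also in the list of proposed clusterin receptors. Resident-type macrophage genes had a median of -0.09 at percentile 6.93 and did not stand apart. Alternative activation genes stood apart at -0.16 (percentile 0.31), with Arg1, the arginase of such macrophages, at 12.8 against 18.8 and Pparg at 11.2 against 7.95. The inflammatory list stood apart at -0.16 (percentile 0.03), with 8 of 24 members at least 1.5-fold lower, including the monocyte attractants Ccl2 (6.64 against 17.9) and Ccl7 (5.76 against 18.3), while Saa3 was higher (15.3 against 9.13). With tissue pieces paired across libraries, the medians ran from -0.52 to -0.08 for macrophage genes and from -2.19 to -0.92 for neutrophil genes. For piece 1 over piece 2 of the same library, macrophage genes had medians of -0.09 in AAV-Clu and 0.26 in AAV-GFP. Those of neutrophil genes were 0.86 and 0.24. The inflammatory median ran from -0.53 to 0.03 and so changed sign. The list no longer stood apart for piece 1 of AAV-Clu against piece 2 of AAV-GFP (percentile 3.90), in the largest pieces (4.59) or in region 1 (1.10). The largest pieces by bins are that same pair, so both settings make nearly the same comparison. Alternative activation genes no longer stood apart with summed MIDs (percentile 3.68) or for piece 2 of AAV-Clu against either piece of AAV-GFP (1.47 and 2.60), nor did macrophage genes for piece 2 of both (10.4).

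Genes of energy metabolism moved by small amounts, and the muscle list did not stand apart. Of 78 measured nuclear-encoded genes of oxidative phosphorylation (OXPHOS), 76 had a log2 ratio under 0. Their median was -0.19 at percentile 0.090, and none of the 78 reached 1.5-fold. Cox8a stood at 457 against 608 CPM and Atp5j2 at 1565 against 2044. The list moved from percentile 0.090 to 6.16 once random lists were matched on gene length as well as expression, and to 1.57 for piece 2 of AAV-Clu against piece 1 of AAV-GFP. Length matching also used coarser bins of expression, and its random lists could draw the list's own members. The move to 6.16 may therefore not be due to length alone. Mitochondrially encoded genes had a median of -0.12 (percentile 25.2), TCA cycle genes -0.12 (percentile 55.4) and fatty acid oxidation genes -0.06 (percentile 87.9), while Ppara was higher, at 19.4 against 12.3. Glycolysis genes had a median of -0.16 at percentile 1.79, as in Pkm (569 against 753) and Eno1 (40.5 against 57.4). Contractile genes had a median of -0.09 at percentile 79.7, with Myl2 at 13620 against 16413 and Ttn at 3284 against 2591. Stress and fetal muscle genes had a median of -0.08 at percentile 64.5. Cytosolic ribosomal protein genes, counted as a check, had a median of -0.23 at percentile 0, which became 5.49 with length matching, under the same limits. Matrix genes of activated fibroblasts had a median of -0.15 at percentile 1.09, and Timp1 (53.3 against 88.3) and Lox (44.8 against 68.8) were lower.

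**Figure D3:**
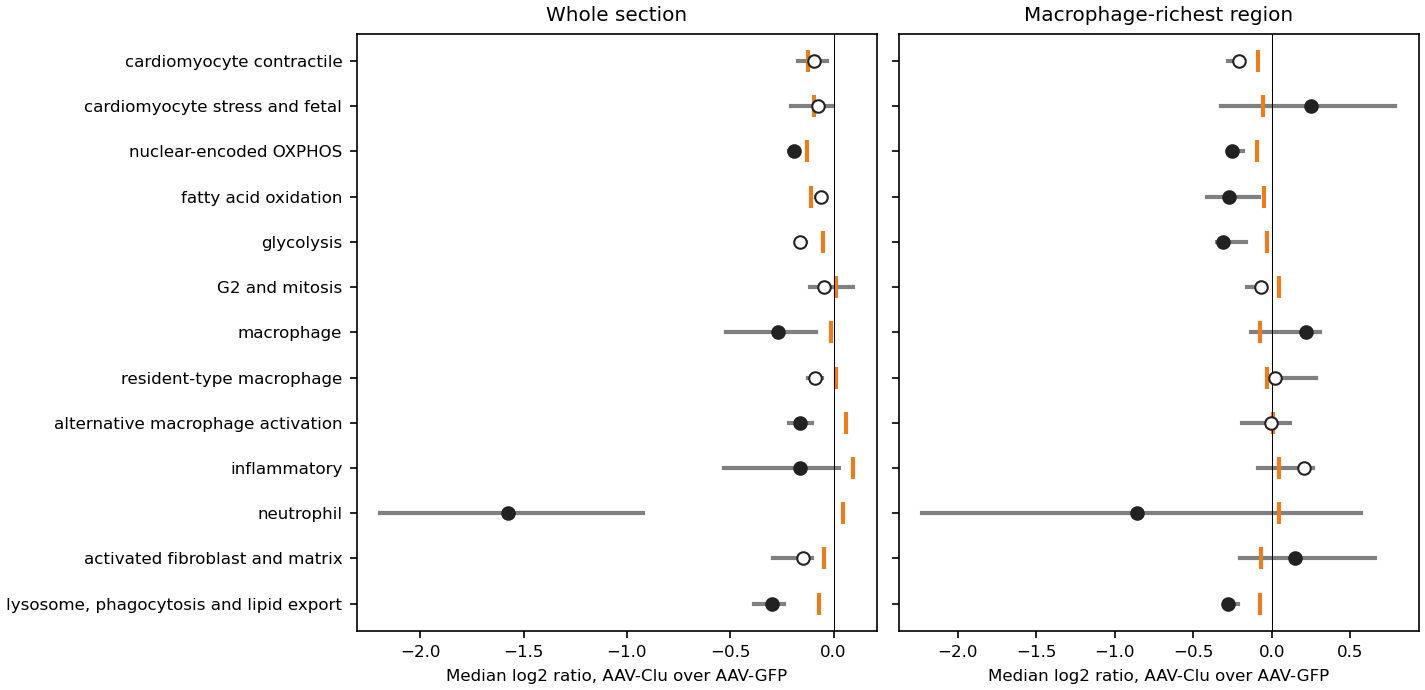
Median log2 ratio (AAV-Clu over AAV-GFP) of 13 gene lists over the whole sections and in the macrophage-richest region. Filled points stand outside percentiles 1 to 99 of random lists, open points inside, grey lines span the 4 pairings of tissue pieces and orange ticks mark the median of the random lists, as for neutrophil genes at -1.58 with pairings from -2.19 to -0.92.

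Bins fell into 8 regions, and region 8, at the end of each tissue piece away from the atrial genes and led by Atp6v0d2, Arg1, Spp1, Il1rn and Gpnmb, was the richest in macrophage genes. It held 2.40% of bins (95% binomial interval 2.24 to 2.56) in the library labelled AAV-Clu and 3.44% (3.26 to 3.63) in the library labelled AAV-GFP. The tissue pieces gave 2.40% and 2.39% against 3.92% and 2.99%. Both AAV-GFP pieces thus lay outside the interval of their own library. The intervals treat bins as independent, which they are not, and do not measure how the share varies between sections. Centring genes within each library draws such shares together, and without it the shares were 2.19% and 3.68%. Region 4, led by Plvap and Vwf, held 15.0% against 10.6% of bins and region 1, led by Rbp7 and Gpihbp1, 28.0% against 34.8%. Region 3, led by haemoglobin genes, held 20.9% against 14.3%, with 22.6% and 19.1% in the AAV-Clu pieces against 9.05% and 19.2% in the AAV-GFP pieces. Its bins were shallow, with medians of 3184 and 3244 MIDs against 4529 and 4645 over the whole libraries. Il31ra and Camk1d were also among its leading genes. Pieces 2 were also close for region 1, at 32.6% in both, where the pieces 1 held 23.7% and 37.1%. Regions 6 and 7, led by Upk1b and by Itih4 and Myh11, held 3.60% against 4.99% and 2.69% against 4.52%. Bins of region 6 were the shallowest, with medians of 832.5 and 830 MIDs, and those of region 7 had 3606 and 2825.5. For region 6 the pieces gave 3.75% and 3.45% against 5.66% and 4.35%. For region 7 the pieces gave 2.90% and 2.47% against 6.27% and 2.86%, so that difference rested mainly on piece 1 of AAV-GFP. Counts of bins are not counts of cells, and the plane of each section sets how much of each region it holds.

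Within region 8 the general macrophage list stood high in the library labelled AAV-Clu, while the phagocyte genes Spp1, Lgals3 and Gpnmb were lower. The macrophage list had a median of 0.22 at percentile 99.99, with 13 of 20 members above 0. Cx3cr1, a chemokine receptor, was higher at 27.2 against 13.5 CPM, and Cd68 was lower at 121 against 196. Selenop was higher too, at 787 against 388, while the resident-type list had a median of 0.02 at percentile 68.9. Spp1 stood at 5134 against 10002, Lgals3 at 736 against 1493 and Gpnmb at 226 against 603, and the lysosome list had a median of -0.28 at percentile 0.010. Spp1 was 1536 in piece 1 of the library labelled AAV-Clu and 8293 in its piece 2, against 9879 and 10211, so the difference rested mainly on piece 1. The inflammatory list had a median of 0.20 at percentile 94.5, with 13 of 24 members above 0. Its chemokine genes went both ways, with Ccl2 lower at 75.8 against 187, Ccl12 lower at 7.74 against 36.7 and Cxcl1 higher at 18.3 against 6.28. The monocyte list had a median of -0.15 and did not stand apart, with Ccr2, the receptor for Ccl2, higher at 38.3 against 20.8 and Ly6c2 lower at 9.73 against 33.1. Alternative activation genes had a median of -0.0032 at percentile 44.2. In pairings of tissue pieces the macrophage median fell to -0.13 for piece 1 of AAV-Clu against either piece of AAV-GFP. For piece 1 over piece 2 of the same library it was -0.23 in AAV-Clu and -0.0080 in AAV-GFP. The lysosome list no longer stood apart with bins of 100 positions (percentile 1.76), without centring (1.26), or for either piece of AAV-Clu against piece 1 of AAV-GFP (2.23 and 1.54).

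OXPHOS, glycolysis and fatty acid oxidation genes stood low in region 8, and stress genes of heart muscle stood high. OXPHOS genes had a median of -0.25 at percentile 0, glycolysis genes -0.31 at percentile 0.010 and fatty acid oxidation genes -0.27 at percentile 0. Random lists in region 8 were matched on expression only. Over the whole sections length matching moved OXPHOS from percentile 0.090 to 6.16. TCA cycle genes (-0.21, percentile 2.19) and mitochondrially encoded genes (-0.042, percentile 71.4) did not stand apart. The glycolytic genes Pkm (519 against 860 CPM), Slc2a1 (20.3 against 35.7) and Eno1 (83.8 against 134) were lower, as was Lpl (366 against 562). Contractile genes had a median of -0.21 at percentile 2.35. They stood apart as lower for piece 1 of AAV-Clu against pieces 1 and 2 of AAV-GFP (0.99 and 0.25) and for piece 2 of both (0.93). The same held with 6 clusters (0.89) and without centring (0.01). Stress and fetal genes had a median of 0.25 at percentile 99.99, with the natriuretic peptide gene Nppb at 190 against 88.0, Xirp2 at 98.3 against 50.7, Myh7 at 194 against 115 and Ankrd1 at 484 against 313. Xirp2 was above both AAV-GFP pieces in piece 1 of AAV-Clu only. Activated fibroblast genes had a median of 0.15 at percentile 99.92, with Cilp (28.2 against 11.6), Thbs4 (43.9 against 23.3) and Ctgf (157 against 87.7) higher. Spp1, also a member, was lower, and so was the summed level of the list, at 14121 against 17960. Thbs4 (71.3 and 19.8 against 17.8 and 32.5 in the pieces) and Ctgf were above both AAV-GFP pieces in piece 1 of AAV-Clu only. Neutrophil genes had a median of -0.86 at percentile 0. For piece 1 over piece 2 of the same library (AAV-Clu, then AAV-GFP), the neutrophil medians were 1.38 and 1.20. Those of stress genes were 0.74 and -0.35 and those of activated fibroblast genes 0.39 and -0.60. All of these were larger in size than the medians between libraries. OXPHOS (-0.01 and 0.08), glycolysis (0.16 and 0.12) and fatty acid oxidation genes (-0.20 and 0.02) differed less within a library. For piece 2 of AAV-Clu against piece 2 of AAV-GFP the stress median was -0.32 and the activated fibroblast median -0.20, and for piece 1 of AAV-Clu against piece 2 of AAV-GFP the neutrophil median was 0.57. In 2 of the 4 pairings fatty acid oxidation (percentiles 5.37 and 31.3) and glycolysis (1.09 and 3.37) no longer stood apart, nor did stress genes without centring (98.2) or activated fibroblast genes for piece 1 of AAV-Clu against piece 2 of AAV-GFP (97.8).

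In region 1, with the highest level of contractile genes, OXPHOS genes had a median of -0.20 (percentile 0.18), with 77 of 78 members under 0, and contractile genes -0.11 (percentile 80.3). Random lists in region 1 were likewise not matched on gene length. Macrophage genes had a median of -0.28, neutrophil genes -1.60, lysosome genes -0.25 and S phase genes -0.36, each at percentile 0. Activated fibroblast genes stood apart there, with a median of -0.22 at percentile 0.010. The levels of the macrophage list itself were 587 against 736 CPM, far under the 8757 against 7902 of region 8.

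Within each library, bins rich in Clu were also rich in macrophage genes and in stress genes of heart muscle. In bins of 100 by 100 positions thinned to 13477 MIDs, the top 10% by Clu held macrophage genes at 2015 CPM against 733 in the other bins of the library labelled AAV-Clu. That ratio was 2.75 (2.71 to 2.80), and it was 2.33 (2.30 to 2.37) in the library labelled AAV-GFP. Across all of these bins the association was weak. Spearman's rho with Clu in AAV-Clu and AAV-GFP was 0.20 and 0.20 for macrophage genes and 0.24 and 0.22 for stress genes. It was 0.11 and 0.11 for inflammatory, 0.06 and 0.10 for alternative activation and -0.16 and -0.31 for OXPHOS genes. Stress and fetal genes were higher in Clu-rich bins, with ratios of 1.85 in the library labelled AAV-Clu and 2.27 in the other, and so were inflammatory genes, with ratios of 1.84 and 1.72. Resident-type genes had ratios of 1.47 and 1.47. The ratio of alternative activation genes had an interval of 1.45 to 1.60 in the library labelled AAV-Clu and of 1.43 to 1.57 in the library labelled AAV-GFP. OXPHOS genes stood at 0.816 and 0.737, contractile genes at 0.823 and 0.750, glycolysis genes at 0.959 and 0.931 and G2 and mitosis genes at 0.919 and 0.866. BMP pathway genes had a ratio of 1.59 in the library labelled AAV-GFP and an interval of 1.12 to 1.18 in the library labelled AAV-Clu. The BMP list holds the atrial gene Bmp10, and the stress list holds Nppa. In region 5, led by atrial genes, Clu itself stood at 404 CPM in AAV-Clu and 706 in AAV-GFP. How far atrial bins make the BMP and stress ratios was not tested. Among bins of region 1 alone the macrophage ratios were 1.06 and 1.26. There several ratios of the library labelled AAV-Clu crossed 1, to 0.918 for inflammatory, 0.966 for alternative activation, 1.00 for OXPHOS, 1.01 for contractile, 1.02 for glycolysis, 1.07 for G2 and mitosis and 0.990 for BMP pathway genes. In the library labelled AAV-GFP glycolysis crossed to 1.01 and the BMP pathway to 0.976.

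**Figure D4:**
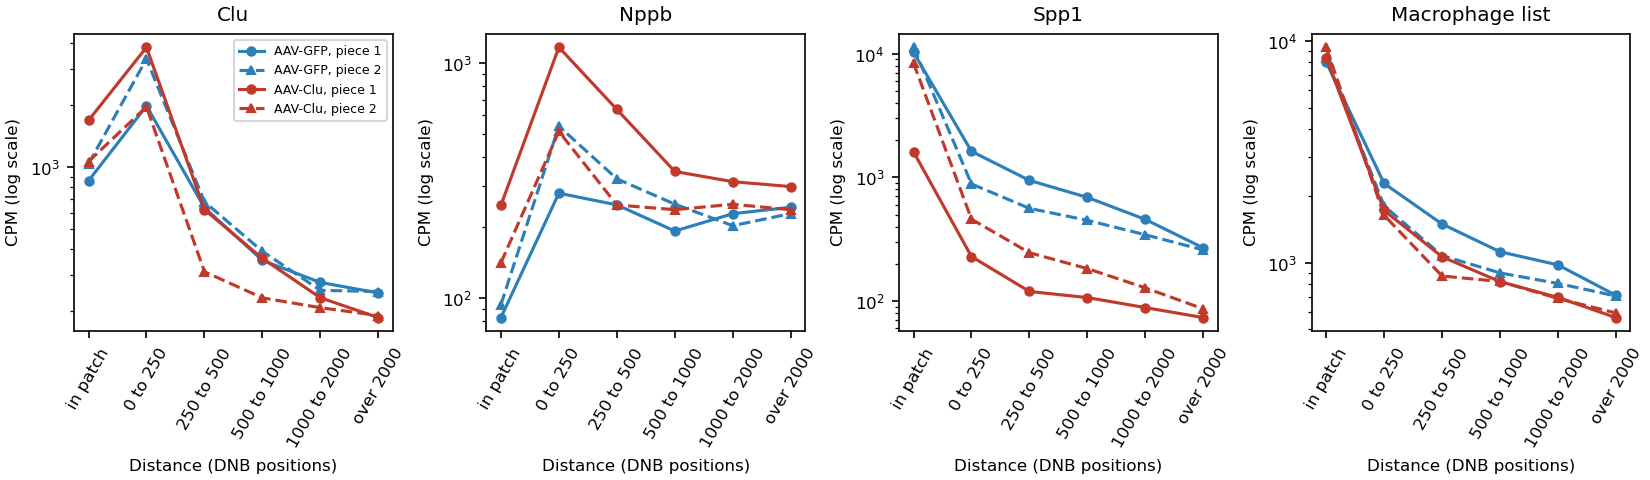
CPM of Clu, Nppb, Spp1 and the macrophage list against distance from the region 8 patch in DNB positions, on log axes, with 1 line per tissue piece and colour for the library label. Clu is highest within 250 positions of the patch in each piece, at 3829 and 1967 for AAV-Clu and 1989 and 3362 for AAV-GFP.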

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

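The pairings of tissue pieces, the shares of bins per piece and the random lists matched on length were chosen after the data were seen; the other alternatives were planned. Exonic MIDs could not be run, because the files hold no such column. With 1 library per group, depth narrows the counting intervals and gives no spread between animals. For the 24 genes at either end of the ratios, no value of the scaling, bin, depth, region 1, equal-weight, largest-piece and pairing alternatives changed sign, with 212 values outside the counting interval and 100 inside it; region 8 alone was not among these, and Nppa (0.29) and Acta1 (0.19) changed sign there. For the 13 leading lists, 234 section-wide values and 96 values in region 8 kept their side of percentiles 1 and 99, though the median changed sign in 4 and 5 of them. Among the other lists 594 values kept their side, 51 of them with a changed sign, 16 passed a percentile limit and 33 fell back from one. Here each pairing selects its own measured members, unlike the ranges in the report. In what follows 1/2 means piece 1 of AAV-Clu over piece 2 of AAV-GFP. The cause of each change was not tested.

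The Clu ratio, 0.848 for the whole sections, was 0.925 (1/1), 0.944 (1/2), 0.762 (2/1) and 0.778 (2/2), 0.770 in region 1 and 0.837 without mitochondrial, haemoglobin and ribosomal protein genes. It stayed under 1 in all of these. Within region 8 the ratio of 1.44 was 1.16 without centring, 1.35 with 6 clusters, 1.42 with 12 and 1.46 with bins of 100 positions. The share of bins in region 8 was 2.61% for AAV-Clu and 4.21% for AAV-GFP with bins of 100 positions, and 2.19% and 3.68% without centring. The AAV-GFP pieces held 3.92% and 2.99%.

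With region 8 alone, medians turned to 0.22 for macrophage, 0.20 for inflammatory, 0.15 for activated fibroblast and 0.093 for fibroblast genes. Stress and fetal genes stood apart at 0.25, glycolysis at -0.31 and fatty acid oxidation at -0.27, the last with its percentile turned from the upper to the lower side. Alternative activation no longer stood apart at -0.0032, and ribosomal protein genes, at -0.059, moved to the upper side. In region 1 the inflammatory median was -0.11, inside the limits, and the activated fibroblast median -0.22, outside them. Activated fibroblast genes also stood apart at -0.15 with random lists not matched, -0.15 with length matching, -0.16 after thinning, -0.18 with equal weight per region, -0.44 for summed MIDs, -0.29 (2/1) and -0.30 (2/2). Glycolysis stood apart at -0.16 with random lists not matched and at -0.16 with length matching. With random lists not matched the TCA cycle, at -0.12, turned to the lower side. OXPHOS no longer stood apart with length matching (-0.19) or for 2/1 (-0.22). Nor did macrophage genes for 2/2 (-0.083), or alternative activation for summed MIDs (-0.12), 2/1 (-0.19) and 2/2 (-0.10). The inflammatory median was 0.025 for 1/2 and 0.031 in the largest tissue piece of each library. By bins these largest pieces are the pieces of 1/2, so both settings make nearly the same comparison, also for erythroid genes. Erythroid genes reversed to -0.93 (1/2) and to -0.92 in the largest pieces, and endocardial genes stood at 0.22 (2/2).

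Within region 8 the macrophage median reversed to -0.13 (1/1) and -0.13 (1/2), the neutrophil median to 0.57 (1/2), the stress median to -0.32 (2/2) and the activated fibroblast median to -0.20 (2/2). Without centring the stress median was 0.10, inside the limits, and the activated fibroblast median was 0.12 (1/2). Contractile genes stood apart at -0.28 (1/1), -0.25 (1/2), -0.21 (2/2), -0.23 with 6 clusters and -0.30 without centring, and resident-type genes at 0.48 (1/2). Lists that no longer stood apart were glycolysis at -0.25 (1/1) and -0.16 (1/2), fatty acid oxidation at -0.19 (2/1) and -0.091 (2/2), and lysosome genes at -0.24 (1/1), -0.25 (2/1), -0.19 with bins of 100 positions and -0.20 without centring.

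For Clu-rich bins the macrophage ratio in AAV-Clu was 2.12 with bins of 50 positions, 3.36 with bins of 200, 2.02 for the top 25%, 2.96 without thinning and 1.06 within region 1. In AAV-GFP it was 1.81, 2.82, 1.80, 2.44 and 1.26 in the same order. Within region 1 of AAV-Clu other ratios crossed 1: alternative activation to 0.966, inflammatory to 0.918, OXPHOS to 1.00, glycolysis to 1.02, G2 and mitosis to 1.07, contractile to 1.01 and BMP pathway to 0.990. In region 1 of AAV-GFP glycolysis crossed to 1.01 and the BMP pathway to 0.976. With bins of 50 positions glycolysis in AAV-Clu stood at 1.00.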

Other observations

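The tests of the pattern in Spp1, Lgals3, S100a8 and S100a9, the test of length for the 12 highest genes, the distance profile and the genes ranked with Clu were chosen after the results were seen; the other tests were written before theirs.

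Clu lay at the edge of the macrophage-richest patch in every tissue piece. Within 250 positions outside the patch, in bins of regions 1 to 4, Clu stood at 3829 and 1967 CPM in the AAV-Clu pieces and at 1989 and 3362 in the AAV-GFP pieces. Beyond 2000 positions it stood at 187 and 191 against 246 and 250. The list of stress and fetal muscle genes peaked at the same edge in each piece, at 18559 and 9193 against 6888 and 12688, and so did each of the 4 members profiled alone (Nppb, Ankrd1, Nppa and Myh7). Nppb stood at 1171 and 513 against 280 and 540, Ankrd1 at 2414 and 1505 against 1162 and 1465 and Nppa at 9158 and 3423 against 1982 and 5988. Spp1 was highest inside the patch, at 1608 and 8398 against 10256 and 11270. Away from the patch, in bins of 200 positions, the genes that went most with Clu in all 4 pieces were Lyz2 (a lysozyme of macrophages), Col1a1, the ribosomal protein gene Rpl41 and the ferritin gene Ftl1, with Spearman's rho from 0.23 to 0.26 for Lyz2 and from 0.21 to 0.31 for Rpl41. Camk1d, Il31ra, Gm42418 and the muscle genes Ttn and Ryr2 went against it, with rho from -0.39 to -0.13 for Gm42418 and from -0.23 to -0.11 for Ttn.

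Of 46 lists with a percentile, 1 stood above and 21 stood below their random lists over the whole sections, and with length matching 3 stood above and 19 below. Length matching, with its coarser bins of expression, took OXPHOS, ribosomal protein, interferon response (percentile 3.26) and antioxidant genes (5.47) inside the limits. It put erythroid (99.3), immediate early (99.7), glycolysis (0.73) and activated fibroblast (0.65) genes outside them. Genes of the epicardium and mesothelium stood above, with a median log2 ratio of 0.53 at percentile 100, 6 of 15 members at least 1.5-fold higher and Msln at 33.4 against 20.2 CPM. In region 8 their median was 1.03 at percentile 100, with Lrrn4 at 17.9 against 4.71 and Krt8 at 32.2 against 11.2. S phase genes had a median of -0.38 at percentile 0, as in Mcm6 at 33.6 against 50.8, while G2 and mitosis genes had -0.05 at percentile 10.3. Atrial genes had a median of -0.68 and monocyte genes -0.37, both at percentile 0, though monocyte genes did not stand apart in region 8. Adipocyte genes had a median of -2.48 at percentile 0, and Ucp1, the uncoupling protein of brown fat, was at 0.097 against 24.0 with 38.3 and 8.55 in the AAV-GFP pieces. The summed level of the adipocyte list had a ratio of only 0.788, since its most abundant members moved less, Cidea with a log2 ratio of -0.27 and Plin4 of 0.16. Other lists at percentile 0 were antigen presenting cell (-0.57), mast cell (-0.67), B cell (-0.54), T and NK cell (-0.29) and platelet (-0.59). Among the alternatives these no longer stood apart in 3 settings each for mast cell and platelet, 2 for T and NK cell and 1 for antigen presenting cell genes. The pairing medians ran from -0.71 to 0.13 for T and NK cell and from -1.34 to -0.04 for platelet genes, and the summed level of mast cell genes had a ratio of 1.02. Lists between percentiles 0.15 and 0.79 were skeletal muscle (-0.21), lymphatic (-0.25), valve and great vessel (-0.21), interferon response (-0.09) and antioxidant (-0.18), which lost that place in 3, 6, 2, 5 and 4 settings in this order. Eln was counted at 909 against 1360 and Gpx3 at 179 against 270. The lists that stayed within the limits had medians of -0.16 for fibroblast, -0.06 for endothelial, 0.02 for endocardial, -0.06 for smooth muscle and pericyte, 0.11 for erythroid, -0.05 for Schwann cell and -0.02 for lung epithelium genes. They were -0.02 for complement, -0.0080 for proposed clusterin receptors, -0.07 for heat shock, -0.14 for unfolded protein response, 0.04 for immediate early, 0.01 for BMP pathway, 0.02 for hypoxia response and -0.09 for p53 target genes. Nuclear-retained RNAs, with 4 members and no percentile by the rule for lists, had a median of 0.53, at percentile 100 with length matching. The sex-linked check list had 0.14, a median that mixes Xist with Y-linked genes and so does not show sex. Xist was counted at 113 against 88.7 CPM and Ddx3y at 216 against 220. Uty had 20 MIDs in each library, Kdm5d 8 and 3 and Eif2s3y 0 and 1.

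The 12 genes highest in the library labelled AAV-Clu stood beside a higher count of Gm42418, at 80872 against 54073 CPM. A trend with genomic length as the whole cause is argued against by the longest 20% of genes, whose median log2 ratio was only 0.14. The 12 highest genes picked in the pairing of both pieces 1 had a median of 1.14 in that of both pieces 2, and those picked in the latter 0.90 in the former, each at percentile 100 of genes matched on expression and length. Reads of ribosomal RNA origin counted on these genes remain a candidate explanation: their median rho with Gm42418 across bins lay at percentile 100 of matched genes in both libraries. A difference made by the vector stays open and was not tested apart from the library, since each group has 1 library.

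OXPHOS genes stood low by a small amount in the library labelled AAV-Clu. Whether less myocardium in the section is the cause was not decided. The list lay at percentile 0.18 within the contractile-richest region. But random lists there were not matched on length, so a length trend could keep the list low there. A trend of the ratio with gene length may account for the low OXPHOS median. Over the whole sections the list lay at percentile 6.16 once random lists were matched on length. That trend had a rho of 0.45 between libraries, 0.40 to 0.44 in the pairings of pieces, and 0.12 and -0.12 between pieces of the same library. An effect of the vector on metabolism cannot be separated here from a difference between libraries.

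Spp1, Lgals3, S100a8 and S100a9 were lower in the library labelled AAV-Clu. A single tissue piece that stands apart is argued against as the whole cause for these genes. Over the 4 pairings of pieces their log2 ratio closest to 0 was -0.72. The genes were picked as among the lowest over the same pieces, so this covers them alone. That the pieces separate is no evidence by itself, as 73.4% of abundant genes do so. Whether a smaller injured area is the whole cause was not decided. In region 1 the median of the 4 genes was -1.12 or lower in each pairing. The log2 ratio of the shares of bins in region 8 was at lowest -0.71, with shares that centring draws together. But the macrophage and lysosome lists had medians of only -0.28 and -0.25 in region 1. Atrial Bmp10 was as low there (-3.71) as over the whole sections (-3.63), and Ucp1 of brown fat stood at 0.10 against 27.0 CPM. Region 1 may thus hold RNA of other tissue and cannot stand for tissue outside the injury. How far levels of the 4 genes within region 8 add to the pattern stays open, since their median there ran from -1.82 to -0.57 over the pairings. A hypothesis for follow-up, to be decided by counts of stained cells in several animals of each group, is that fewer neutrophils and Spp1-rich phagocytes may have been present in the sections labelled AAV-Clu, but other differences between the libraries, and the label itself at Clu ratios of 0.762 to 0.944 over the pairings, stay open.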
